A study of Mus musculus with 8 samples.

How the data were processed

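RNA sequencing was used to compare 8 pancreatic tumours of C57BL/6 mice, 4 from mice given saline and 4 from mice given TLQP21, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit, libraries were built with the NEBNext Ultra RNA kit, and paired ends of 150 bp were sequenced on an Illumina NovaSeq instrument. The deposited table held whole-number read counts per gene, not normalised, for 54532 genes. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.32.0 were used with mouse genome build GRCm38 (mm10). The strand setting of the counting and the annotation release were not given in the sources used here. Counts of genes that overlap on opposite strands are therefore uncertain, as are counts of immunoglobulin segments, hemoglobins, trypsins, Hspa1a and Hspa1b, and the H2 genes, which have near-identical copies. Of the gene identifiers, 54495 were found in the GENCODE M21 annotation of GRCm38, and 53585 of these (98.3%) had the same chromosome, start and end. Gene positions are given 1-based on GRCm38. No row lacked a gene name, and 21886 genes had no count in any library.

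From the counts, genes were tested with edgeR 4.0.16 in R 4.3.3, with its default filter on low counts applied by group (18238 genes kept, 14780 of them protein-coding), trimmed-mean (TMM) scaling and the quasi-likelihood test of TLQP21 against Saline, without covariates. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM (counts scaled to equal library totals) after TMM scaling, as mean ± SD with n = 4 per group, and log2 fold changes are TLQP21 minus Saline with their SE. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run as other tools. DESeq2 gave an adjusted p for 32380 genes and none for 22152, which were left out of its counts.

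The design, the alternatives and 44 gene lists (pathways, immune and stromal cell types, and cells of neighbouring tissues) were chosen before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, all adjusted over the lists. A list's level was the mean log2 CPM of its tested members (prior count 2), and levels and per-library measures were compared by exact two-sided permutation tests over 70 assignments, whose smallest p is 0.0286. Of the listed genes, 4 were not found under their names (Pap, Hbb-b1, Hbb-b2 and Ahsp). Genes named in the text followed a rule. Where fewer than 5 genes passed the threshold in a direction, it took the 10 with the smallest unadjusted p in that direction. To these it added Vgf, C3ar1 and, per list, up to 4 tested members with the smallest unadjusted p, and for lists of other tissues the most abundant member. Genes named along the split by Xist and Y-linked transcripts were chosen after their values were seen.

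The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Nothing in the labels says that equal replicate numbers mark shared animals or days, and a check of the data did not pair them. No pair of libraries was identical: the lowest chi-square per degree of freedom over genes between any pair was 19.0. Alternatives covered other scalings, gene filters, tools, a replicate block, the acinar genes left out or as a covariate, protein-coding genes only, looser thresholds, another prior count and each library left out in turn. Added after seeing the data were the sex-linked split as a covariate, libraries thinned to the smallest total, and Saline 2 and TLQP21 4 left out together. Saline 2 has Xist and TLQP21 4 Y-linked transcripts, so leaving out both makes that split uneven between the treatments. Leaving out a single library does so to a lesser degree.

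The gene test was tested on simulated data with the means and library sizes of these 8 libraries, with 50 genes changed at each fold size among 18238. It recovered 2 genes at 1.5-fold (4%), 26 at 2-fold (52%), 39 at 3-fold (78%) and 41 at 4-fold (82%), with 11 false calls among 18038 unchanged genes. With no change simulated it made 1 call, and 4.68% of genes had an unadjusted p under 0.05, against 3.06% in the real comparison. Simulated genes varied independently, without the split by sex-linked transcripts or libraries that stand apart. The recovery rates therefore need not hold for the real libraries.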

Results

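The libraries were made from orthotopic tumours of C57BL/6 mice grown from KPC cells, a mouse pancreatic ductal adenocarcinoma line. The mice had received saline or TLQP21, a peptide cut from the neurosecretory protein VGF, for 2 weeks. The series asks which transcripts accompany the reduced growth of tumours that the submitters describe under the peptide. Each group held 4 libraries. Whole tumours were sequenced, so each library mixed tumour cells with stroma, immune cells and neighbouring tissue.

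Summed gene counts ran from 28.4 to 29.0 M counts in Saline (mean 28.7 ± 0.295, SD, n = 4) and from 29.03 to 33.5 M in TLQP21 (31.4 ± 2.15). Every TLQP21 library was deeper than every Saline library (exact two-sided permutation p = 0.0286, the smallest possible; 0.143 adjusted over 5 measures). The other measures gave exact p between 0.571 and 0.886. Acinar genes, which encode digestive enzymes of the normal pancreas, took 3.46 ± 2.41% of counts in Saline and 2.61 ± 1.26% in TLQP21, with 6.91% in Saline 4. Transcripts of the mitochondrial genome took 2.05 ± 0.215% and 2.13 ± 0.450%, with 2.80% in TLQP21 4. The 20 most abundant genes took 7.12 ± 0.785% and 7.04 ± 0.263%, and 25830 ± 700 and 25894 ± 396 genes were detected. Hepatocyte genes took 0.644% of counts in Saline 2 and 0.0321 to 0.0748% in the other libraries. Rank correlations between libraries lay between 0.942 and 0.962.

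Xist, the RNA of the inactive X chromosome, had 9960 to 10625 reads in libraries 1 and 2 of each group and 0 to 14 in libraries 3 and 4. The summed reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 1 to 20 in the former and 2027 to 2247 in the latter. Both treatment groups thus held 2 libraries of each kind, which the labels do not mention. The first principal component of log2 CPM held 32.4% of the variance and the second 20.2%. No component separated the treatments, with exact permutation p from 0.143 to 0.743. On these 2 components TLQP21 4 and Saline 4 lay farthest from the centre, and on the third Saline 2 did, with a score of 36.8. Rank correlations of Saline 2 with the other libraries were 0.942 to 0.951.

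**Figure D1:**
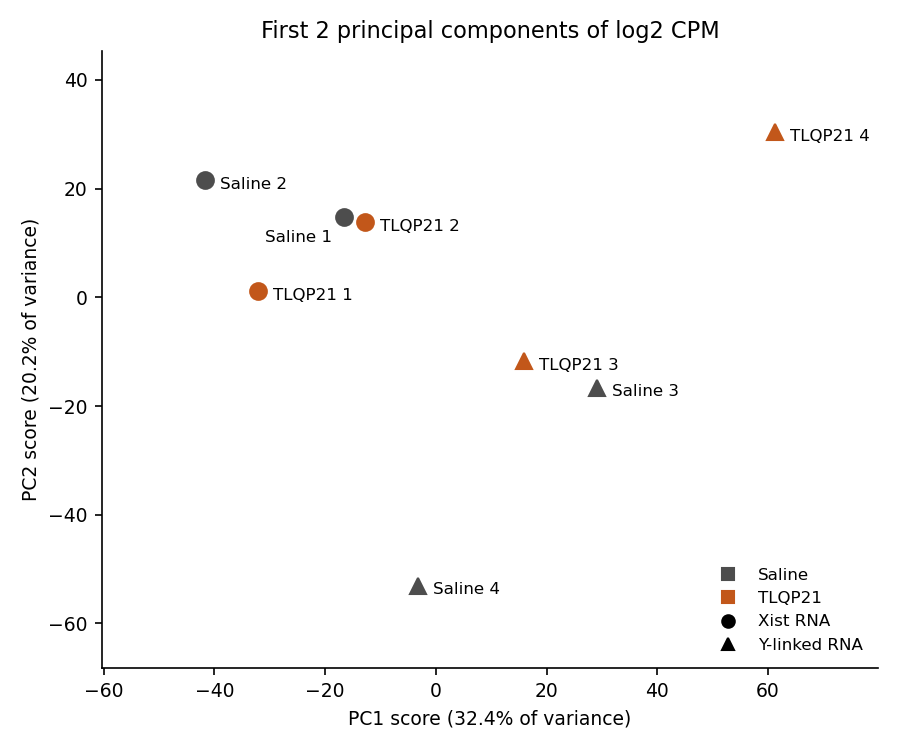
Each point is a library, placed by its scores on the first principal component (horizontal axis, 32.4% of variance) and the second (vertical axis, 20.2%) of log2 CPM. Grey points are Saline and orange points TLQP21, with circles for libraries with Xist RNA and triangles for those with Y-linked RNA; treatments intermingle, while the 4 libraries with Xist lie left of the 4 with Y-linked RNA.

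Between TLQP21 and Saline tumours, no single gene passed the threshold in the edgeR test. Among the genes with the smallest p that lay lower in TLQP21, Blvrb, a biliverdin and flavin reductase, was at 33.99 ± 5.44 CPM in Saline and 21.7 ± 1.36 in TLQP21 (log2 fold change -0.65, SE 0.13, n = 4 per group). Cd69, an early activation marker of lymphocytes, was at 5.14 ± 0.177 and 3.03 ± 0.209 CPM (-0.76, SE 0.16). Gpr141, an orphan receptor, was at 8.60 ± 2.94 and 3.49 ± 0.669 CPM (-1.30, SE 0.27), and Slamf7, a receptor of lymphoid and myeloid cells, at 20.9 ± 4.68 and 11.5 ± 1.602 (-0.86, SE 0.18). Plek, a protein kinase C substrate of blood cells, was at 135 ± 10.4 and 83.7 ± 18.6 CPM, and Adgre1, which encodes the macrophage antigen F4/80, at 128 ± 5.80 and 92.2 ± 14.3. The ranges of the groups did not overlap for any of these 6 genes, nor for Rnf19b, a ubiquitin ligase (126 ± 12.6 and 89.6 ± 11.8 CPM), or Gm45716, a predicted gene (-1.02). Within the libraries with Xist and within those with Y-linked transcripts, log2 ratios were -0.54 and -0.74 for Blvrb, -0.73 and -0.79 for Cd69, -1.49 and -1.01 for Gpr141, -0.96 and -0.73 for Slamf7, -0.54 and -0.85 for Plek, and -0.40 and -0.55 for Adgre1. Because the groups did not overlap for these genes, the sign of the ratios was fixed in advance, and only their size could vary.

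Immunoglobulin genes were among those with the smallest p in both directions. The heavy-chain variable segment Ighv7-4 was at 0.936 ± 0.301 CPM in Saline and 0.0723 ± 0.0448 in TLQP21 (-3.64, SE 0.45), and the constant region Ighg3 at 100.5 ± 56.3 and 18.3 ± 13.7. Ighm was at 804 ± 213 and 307 ± 170 CPM (-1.39, SE 0.34), without overlap, with log2 ratios of -1.39 and -1.38 within the libraries with Xist and with Y-linked transcripts. Without overlap, the sign of the Ighm ratios was fixed in advance. Another segment, Ighv1-39, was higher in TLQP21 at 8.47 ± 12.2 CPM against 0.790 ± 0.842, and TLQP21 1 alone had 26.8. Reads of such segments can be split among near-identical copies, so these values are uncertain.

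Among the genes with the smallest p that lay higher in TLQP21, Serpine2, a secreted protease inhibitor, was at 111 ± 9.90 CPM in Saline and 143 ± 20.6 in TLQP21 (0.37, SE 0.12). Cdh17, an intestinal cadherin, was at 197 ± 16.8 and 244 ± 23.5 CPM (0.31, SE 0.10), Clic3 at 5.20 ± 0.321 and 7.18 ± 0.509, and Fbxo36 at 1.89 ± 0.254 and 3.07 ± 0.401. None of these overlapped between groups. Within the libraries with Xist and with Y-linked transcripts, log2 ratios were 0.24 and 0.50 for Serpine2 and 0.25 and 0.37 for Cdh17, with a sign fixed in advance by the lack of overlap. The other 5 had means below 1 CPM, with log2 fold changes of 1.47 for Lime1, 1.28 for Gm4824, 0.92 for Nos1, 1.03 for Lypd1 and 0.82 for Gm48804.

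Of 18238 genes tested with edgeR, 0 were higher and 0 lower in TLQP21, and 558 had an unadjusted p under 0.05 (145 higher, 413 lower), where chance alone would give about 912. The smallest adjusted p was 0.238, for Ighv7-4, and the next was 0.9999. DESeq2 called 4 genes lower and 0 higher, with 745 at an unadjusted p under 0.05: Ighv7-4 (-3.71, adjusted p = 0.000344), Gpr141 (-1.30, 0.0212), Blvrb (-0.65, 0.0465) and Cd69 (-0.76, 0.0465). Limma's voom with sample quality weights called Ighv7-4 alone (-3.63, adjusted p = 0.0477). The groups did not overlap for 302 genes (1.66%), against 2.86% by chance. For 14518 genes (79.6%) the 95% interval of the fold change lay within 2-fold in both directions. In simulated data of this size, 52% of 2-fold and 4% of 1.5-fold changes were recovered. Those genes varied independently, unlike genes in these libraries, so real recovery may differ.

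On GRCm38, Blvrb (ENSMUSG00000040466) lies on chromosome 7 from 27447978 to 27466144, and Cd69 (ENSMUSG00000030156) on chromosome 6 from 129267325 to 129275436. Gpr141 (ENSMUSG00000053101) lies on chromosome 13 from 19749682 to 19824257, and Adgre1 (ENSMUSG00000004730) on chromosome 17 from 57358691 to 57483527. All 4 are annotated as protein-coding. Ighv7-4 (ENSMUSG00000076668) is a variable-segment gene on chromosome 12 from 114222788 to 114223328.

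**Figure D2:**
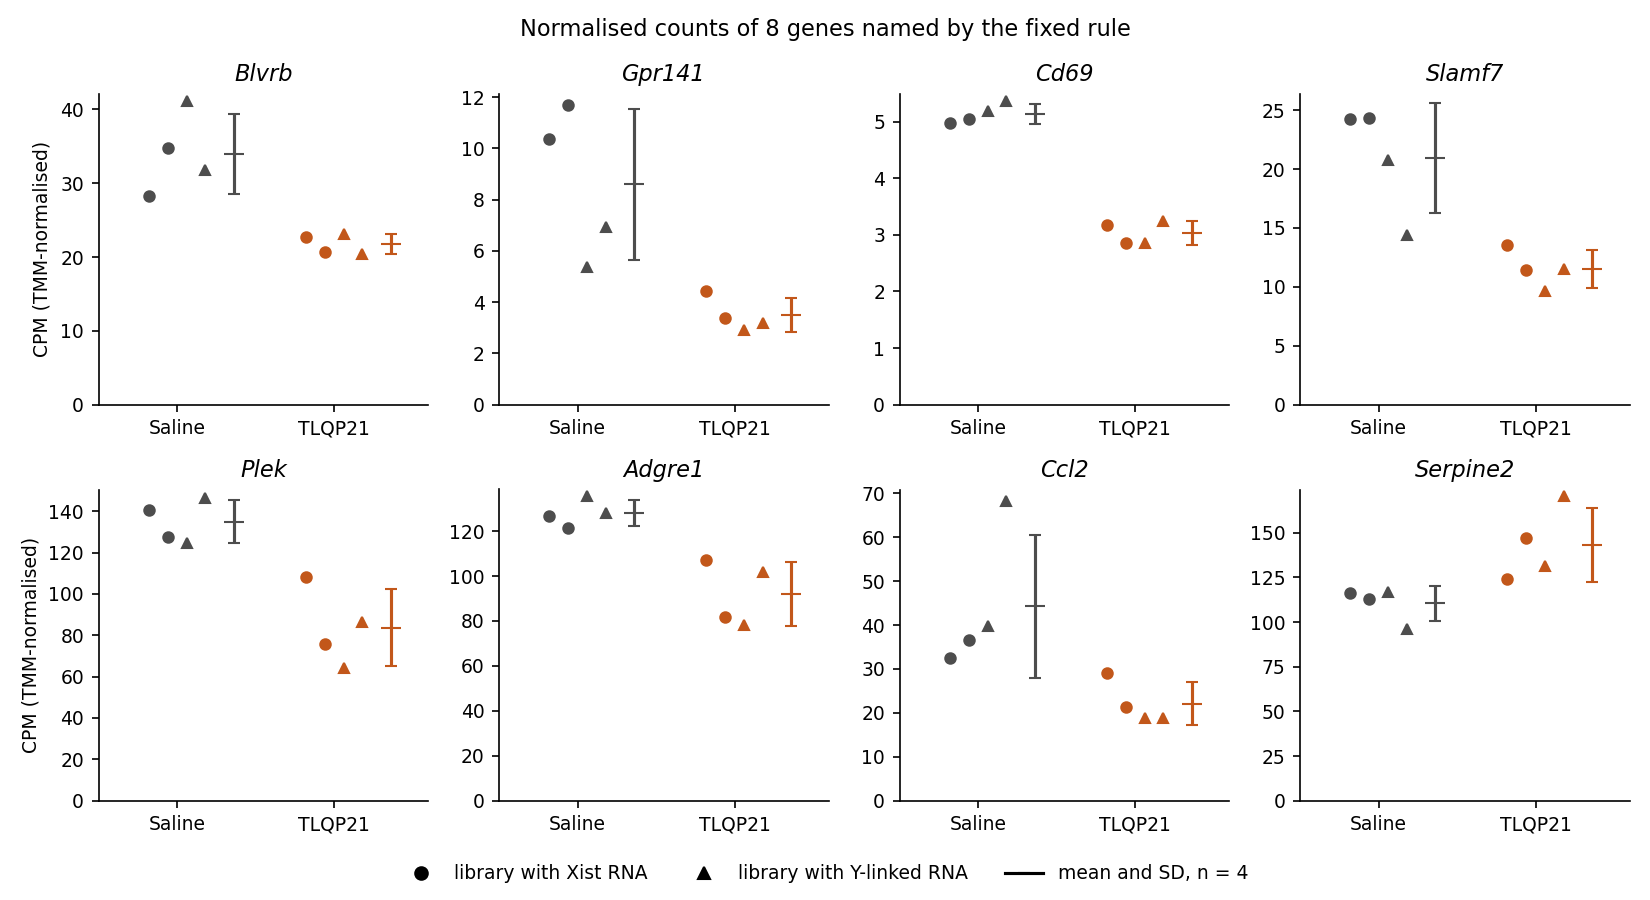
TMM-normalised CPM (vertical axes, from 0) of 8 genes in each Saline (grey) and TLQP21 (orange) library, with circles for libraries with Xist RNA, triangles for those with Y-linked RNA, and bars for the mean and SD of 4 libraries. For Blvrb, Gpr141, Cd69, Slamf7, Plek, Adgre1 and Ccl2 every TLQP21 library lay below every Saline library, and for Serpine2 every TLQP21 library lay above; none passed the edgeR threshold over all genes.

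Vgf, which encodes the precursor of TLQP21, was close to absent from these tumours, with 24 reads over the 4 Saline libraries and 44 over the 4 TLQP21 libraries (0.215 ± 0.117 and 0.355 ± 0.175 CPM, exact permutation p = 0.229). It did not pass the filter on low counts. C3ar1, a complement receptor reported as a receptor of TLQP21 in rodents, was at 53.6 ± 12.3 CPM in Saline and 57.5 ± 19.2 in TLQP21 (0.10, SE 0.24). Its direction turned without Saline 3 (-0.02) and without TLQP21 1 (-0.13). C3, the source of the ligand C3a, was at 1890.1 ± 452 and 1290 ± 401 CPM (-0.55, SE 0.24). The list of the precursor and reported receptors differed by -0.19 in mean level, with 6 of 8 tested members below 0, and did not pass limma's camera at the preset correlation (adjusted p = 0.0561) or with an estimated one (adjusted p = 0.771). Without Saline 3 (-0.23, adjusted p = 0.0206) and without TLQP21 1 (-0.29, 0.0114) it passed at the preset correlation, and the difference was -0.06 without Saline 1, -0.13 without Saline 4 and -0.02 without TLQP21 4. No member passed adjusted over the list alone.

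Genes of neutrophils and of inflammatory signalling lay lower in the TLQP21 tumours. All 18 neutrophil genes had log2 fold changes below 0, and their mean level was 4.44 ± 0.76 log2 CPM in Saline and 3.41 ± 0.58 in TLQP21 (difference -1.04, n = 4 per group). Clec4e, a receptor for damaged cells and mycobacterial glycolipid, was at 75.4 ± 34.5 and 24.9 ± 18.4 CPM. The calprotectin subunit S100a9 was at 159 ± 114 and 65.8 ± 26.8, S100a8 at 119 ± 87.4 and 51.8 ± 18.5, and the granule protein Ltf at 278 ± 66.4 and 176 ± 65.9. Of 28 cytokine and chemokine genes, 26 lay below 0 (difference in level -0.62), among them the monocyte chemoattractant Ccl2 (44.3 ± 16.3 and 22.1 ± 4.89 CPM), the neutrophil growth factor Csf3 (11.1 ± 7.20 and 3.99 ± 1.55), Ccl20 (-0.69) and the NF-kappaB inhibitor Nfkbia (-0.62). No member of either list passed over all genes or adjusted over the list alone. Limma's camera called both lists lower at the preset correlation (adjusted p = 7.67e-13 and 4.04e-11). With an estimated correlation the adjusted p = 0.658 for each, and exact permutation of the levels gave p = 0.0571 and 0.0857. Saline 4 had the highest level of both lists, and without it the differences were -0.66 and -0.36. TLQP21 1, at 4.06 and 4.72 log2 CPM, lay within the range of the other Saline libraries in both lists (4.02 to 4.10 and 4.63 to 4.72). Saline 4 also had the highest acinar share and immediate-early and heat-shock level (6.94 log2 CPM, against 5.68 to 6.10 in the other Saline libraries). Within the libraries with Xist and within those with Y-linked transcripts, neutrophil genes differed by -0.71 and -1.37 and cytokine genes by -0.28 and -0.95. Log2 ratios were -0.45 and -1.52 for Ccl2, whose groups did not overlap, so that their sign was fixed in advance. Whether list differences were unequal between the 2 kinds was not tested.

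Interferon-response and antigen-presentation genes also lay lower in TLQP21. Of 32 interferon genes, 31 were below 0 (difference in level -0.33), among them the guanylate-binding protein Gbp5 (138 ± 42.3 and 81.0 ± 23.7 CPM), Ifit2 (41.5 ± 6.55 and 30.8 ± 4.05) and the antiviral enzyme Rsad2 (34.4 ± 7.32 and 23.1 ± 6.92). Of 21 antigen-presentation genes, 20 were below 0 (-0.26), among them Nlrc5, the activator of class I genes (111 ± 8.99 and 92.7 ± 13.1 CPM), the class II chain H2-Eb1 (741 ± 103 and 572 ± 122) and its chaperone Cd74 (-0.29). No member passed over all genes or adjusted over the list alone. Camera called both lists lower at the preset correlation (adjusted p = 7.67e-13 and 1.45e-09). With an estimated correlation the adjusted p = 0.710 for each, and exact permutation p-values were 0.114 and 0.171. Without TLQP21 4 the antigen-presentation difference was -0.15, and within the libraries with Xist and with Y-linked transcripts it was -0.12 and -0.39. The interferon difference within these 2 kinds was -0.34 and -0.32. The exact permutations did not take this split into account. With Saline 2 and TLQP21 4 both left out, chosen after seeing the data, the differences were -0.19 and -0.10 and both calls stood (adjusted p = 0.000224 and 0.0244). In that fit the split was uneven between the treatments.

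Macrophage and complement genes followed the same direction. Of 24 macrophage and monocyte genes, 21 lay below 0 (difference in level -0.31). Besides Adgre1, these included the monocyte marker Ly6c2 (21.2 ± 5.57 and 9.22 ± 5.31 CPM) and the inducible nitric oxide synthase Nos2 (114 ± 63.3 and 43.0 ± 28.5). Adjusted over the list alone, Adgre1 passed in the edgeR test (adjusted p = 0.0468), and over all genes it did not. Of 22 complement genes, 18 lay below 0 (-0.26), among them C2 (13.0 ± 1.23 and 9.39 ± 2.47 CPM) and C3. The member Hc, a liver-secreted complement component, was at 47.7 CPM in Saline 2, the library with hepatocyte transcripts, and at 0.756 to 2.04 in the other libraries; its direction turned without Saline 2 (0.24). No complement gene passed over all genes or adjusted over the list alone. Camera called both lists lower (adjusted p = 6.85e-06 and 0.000104 at the preset correlation). With an estimated correlation the adjusted p = 0.710 for each, and exact permutation of the levels gave p = 0.229 and 0.257. Within the libraries with Xist and with Y-linked transcripts the macrophage difference was -0.18 and -0.44. Without TLQP21 1 the macrophage difference was -0.48. The complement difference was -0.15 without Saline 2 and -0.17 without TLQP21 3. With Saline 2 and TLQP21 4 both left out, the macrophage call (-0.15, adjusted p = 0.0684) and the complement call (-0.13, adjusted p = 0.106) were lost. That fit also left the split by sex-linked transcripts uneven between the treatments, so the losses cannot be ascribed to these libraries alone.

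Red cell genes lay lower and contractile stromal genes higher in TLQP21. All 14 tested erythrocyte and platelet genes lay below 0 (levels 3.78 ± 1.34 and 2.92 ± 1.05 log2 CPM, difference -0.87), among them the globins Hbb-bt (73.0 ± 29.3 and 33.7 ± 12.8 CPM) and Hba-a1 (309 ± 147 and 159.8 ± 64.4). This difference was -0.40 without Saline 3 and -0.45 without TLQP21 2, and -0.51 and -1.23 within the libraries with Xist and with Y-linked transcripts. It was -1.64 with Saline 2 and TLQP21 4 both left out, a fit with the split by sex-linked transcripts uneven between the treatments. Between libraries with Y-linked transcripts and those with Xist, erythrocyte and platelet genes differed by 1.92, more in size than between treatments. Of 16 myofibroblast and smooth muscle genes, 15 lay above 0 (4.39 ± 0.13 and 4.56 ± 0.09 log2 CPM, difference 0.18), among them smooth muscle actin Acta2 (114 ± 21.2 and 142 ± 11.9 CPM) and the pericyte proteoglycan Cspg4 (21.4 ± 1.11 and 24.9 ± 2.64). Within the 2 kinds of library the myofibroblast difference was 0.32 and 0.03. No member of either list passed over all genes or adjusted over the list alone. Camera called both lists at the preset correlation (adjusted p = 1.27e-05 and 6.79e-05). With an estimated correlation the adjusted p = 0.710 and 0.658, and exact permutation of the levels gave p = 0.371 and 0.0571.

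**Figure D3:**
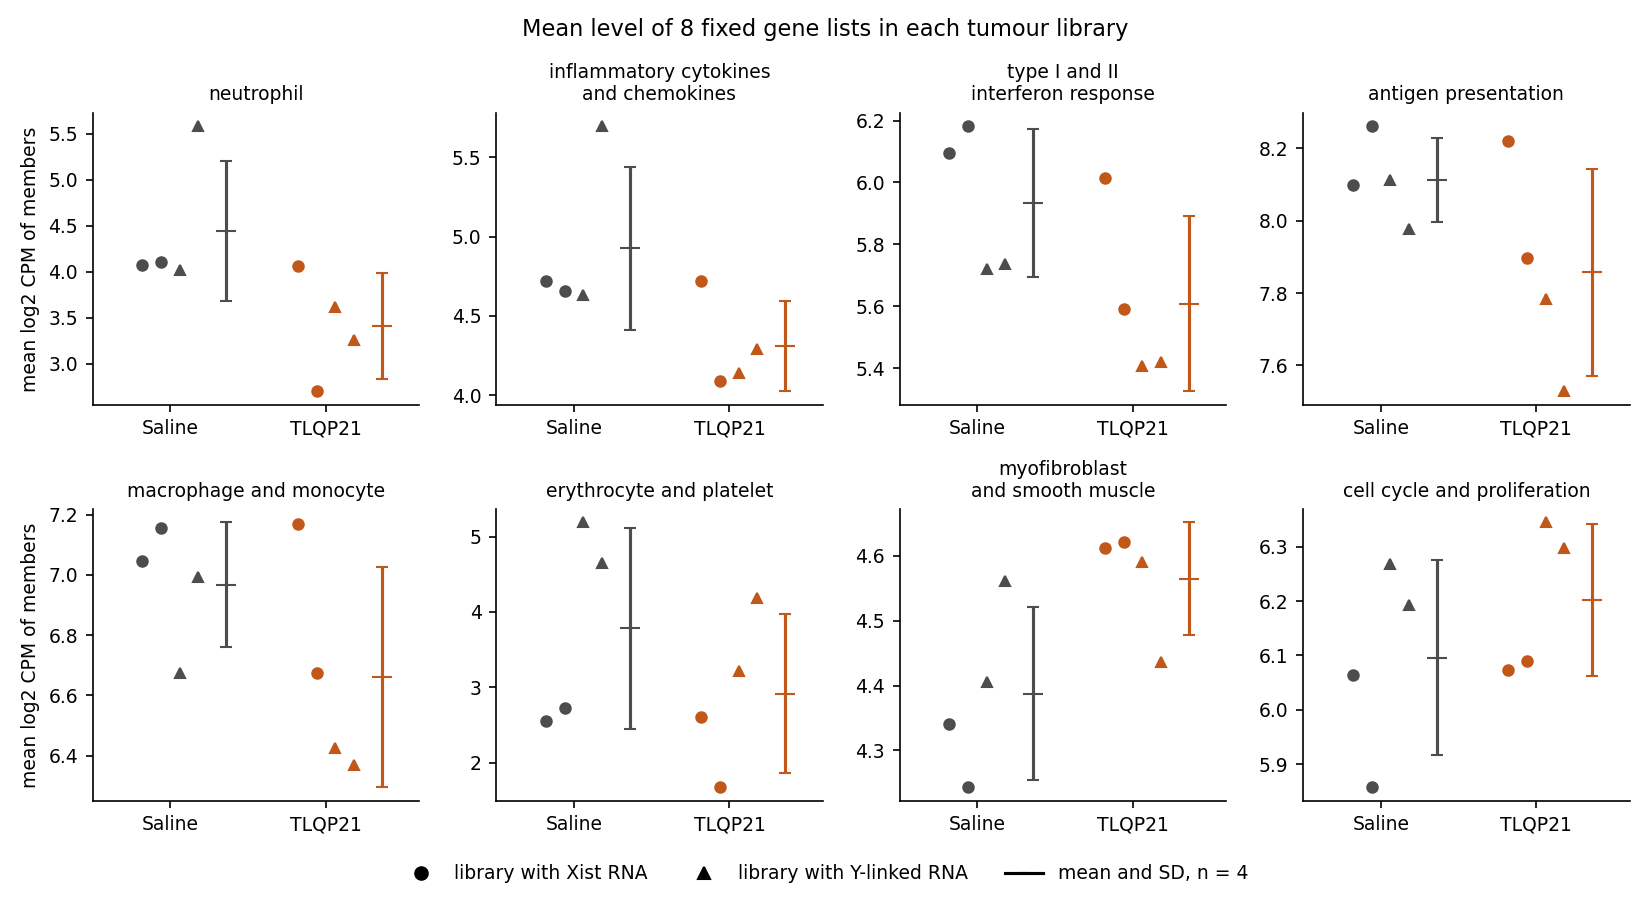
Mean log2 CPM of the tested members of 8 gene lists (vertical axes, which do not start at 0) in each Saline (grey) and TLQP21 (orange) library, with circles for libraries with Xist RNA, triangles for those with Y-linked RNA, and bars for the mean and SD of 4 libraries. Saline 4 stands at 5.58 for neutrophil genes, above 4.02 to 4.10 in the other Saline libraries, and no list separates the groups completely.

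The remaining 11 of the 19 lists that passed at the preset correlation (15 lower, 4 higher, of 44) each lost the call without at least 1 library. Cell cycle genes lay higher in TLQP21 (25 of 30 above 0, difference 0.11), among them Ube2c (84.2 ± 9.33 and 98.4 ± 3.27 CPM) and the mitotic kinase Aurka (33.7 ± 3.60 and 40.4 ± 3.70). Fibroblast and collagen genes differed by 0.08 (19 of 30 above 0; periostin, Postn, 241 ± 48.5 and 311 ± 51.9 CPM), and ribosomal protein genes by 0.05 (20 of 32 above 0; Rplp0 0.17). All 33 tested acinar genes lay below 0 (-0.38), the most abundant being Ctrb1, a chymotrypsinogen (8767 ± 6133 and 6458 ± 3046 CPM), beside the acinar shares given above. Unfolded protein response genes differed by -0.17 (20 of 22 below 0; Ppp1r15a -0.56) and p53 targets by -0.16 (17 of 22; the cell cycle inhibitor Cdkn1a -0.41). Immediate-early and heat-shock genes differed by -0.26 (19 of 22; Junb -0.39), with Hspa1a at 285 and Hspa1b at 689 CPM in Saline 4. B cell and plasma cell genes differed by -0.28 (18 of 23). Against that direction Ighg2c changed by 1.22, with 244 CPM in TLQP21 1 and 36.5 to 65.1 in the other TLQP21 libraries. The member Ighm, given above, lay lower. T cell genes differed by -0.16 (16 of 26, with Cd4 -0.67 and Il2ra -0.72) and checkpoint genes by -0.15 (15 of 18, with Cd274, which encodes PD-L1, -0.74). Of 11 tested hepatocyte genes, 10 lay below 0 (-1.48), and 7 passed adjusted over the list alone (smallest adjusted p = 0.0296 by edgeR), among them Hpx at 666, Ahsg at 316, Apoa1 at 258 and Serpina1b at 133 CPM in Saline 2. In the other 10 lists no gene passed over all genes or adjusted over the list alone. With an estimated correlation the adjusted p for these 11 lists lay between 0.710 and 0.813, and exact permutation p of the levels between 0.0857 and 0.657.

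Calls of these 11 lists depended on single libraries as follows. Without Saline 1, the T cell (-0.14) and checkpoint (-0.14) calls were lost. Leaving out Saline 2 ended those of cell cycle (0.03), fibroblast (0.04), T cell (-0.13), B cell (-0.03), checkpoint (-0.12) and hepatocyte genes (0.08). Leaving out Saline 3 ended those of ribosomal (0.02), fibroblast (-0.00074) and T cell genes (-0.09). Without Saline 4, the p53 (-0.08), ribosomal (0.03), unfolded protein (-0.08), immediate-early (0.01), checkpoint (-0.16) and acinar (0.05) calls were lost. Without TLQP21 1, ribosomal (0.04), immediate-early (-0.17), fibroblast (0.02) and hepatocyte (-1.48) calls were lost. Leaving out TLQP21 2 ended the p53 (-0.16), ribosomal (0.02), immediate-early (-0.11), T cell (-0.16), B cell (-0.12), checkpoint (-0.13), acinar (-0.20) and hepatocyte (-1.51) calls. Without TLQP21 3, p53 (-0.17), T cell (-0.10), checkpoint (-0.09) and hepatocyte (-1.30) calls were lost. Without TLQP21 4, T cell (-0.09), B cell (-0.13) and acinar (-0.13) calls were lost. Other single libraries moved a called difference by over 1.5 times and left the call. For acinar genes it was -0.65 without Saline 1, -0.62 without Saline 3 and -0.67 without TLQP21 1, and for B cell genes -0.46 without Saline 3 and -0.54 without TLQP21 1. T cell genes differed by -0.27 without Saline 4 and -0.27 without TLQP21 1, and checkpoint genes by -0.23 without TLQP21 1. Immediate-early genes differed by -0.40 without Saline 2 and -0.42 without TLQP21 4, ribosomal genes by 0.08 and 0.08, and fibroblast genes by 0.19 without Saline 4. The cell cycle difference was 0.16 without Saline 3, 0.06 without TLQP21 3 and 0.07 without TLQP21 4. Without Saline 2 and TLQP21 4 together, the calls of cell cycle (-0.01), fibroblast (0.04), T cell (-0.06), B cell (0.11), checkpoint (-0.12), acinar (-0.07) and hepatocyte genes (-0.02) were lost. Immediate-early and ribosomal genes differed by -0.57 and 0.11 in that fit, which left the split by sex-linked transcripts uneven between the treatments.

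Tumour epithelium, vessel, nerve and metabolic gene lists did not pass. Ductal and tumour epithelial genes differed by -0.04, with Krt19 at 1021 ± 58.2 and 1148 ± 128 CPM and Lcn2, a neutrophil-associated iron carrier, at 285 ± 98.0 and 156 ± 48.1. The differences were 0.0042 for epithelial-mesenchymal transition (Hmga2 0.25), -0.0037 for RAS-MAPK output, -0.04 for TGF-beta and YAP output and -0.01 for Wnt, Notch and Hedgehog output. Endothelial genes differed by -0.02 (Prox1 -0.73), matrix proteases by -0.09 (Mmp9 -0.67) and hypoxia and glycolysis by -0.05 (Vegfa 758 ± 153 and 639 ± 55.9 CPM). Neuropeptide and pain mediator genes differed by -0.06 (Ramp1, part of the CGRP receptor, 35.5 ± 1.37 and 41.7 ± 3.50 CPM; the bradykinin receptor Bdkrb1 -0.75). Nerve growth and axon guidance differed by -0.07 (Sema4d -0.25) and Schwann cell and nerve fibre genes by -0.01 (Mbp -0.12). Cholesterol and fatty acid synthesis differed by 0.05, lipolysis and fatty acid oxidation by -0.06, nuclear-encoded oxidative phosphorylation by -0.04 and mitochondrial genome transcripts by -0.06 (mt-Nd3 16.0 ± 2.89 and 10.8 ± 1.16 CPM, without overlap). Among other cells, cytotoxic and NK genes differed by -0.23 (Ccl5 -1.55), dendritic by -0.07 (Naaa -0.24), mast cell and eosinophil by -0.23, adipocyte by -0.21 and mesothelium by 0.15. Islet genes differed by -0.14, acinar injury by -0.17, intestinal epithelium by -0.14 and skeletal muscle by -0.09. No gene in these lists passed over all genes or adjusted over the list alone. Some of these lists passed at the preset correlation without 1 library. The cytotoxic and NK list passed without Saline 3 (-0.34, adjusted p = 0.0172), Saline 4 (-0.38, 0.00118) and TLQP21 1 (-0.40, 0.00457), and its difference was -0.12 without Saline 1, -0.08 without Saline 2, -0.11 without TLQP21 3 and -0.13 without TLQP21 4. The mast cell and eosinophil difference was -0.38 without Saline 2, -0.10 without Saline 4 and -0.08 without TLQP21 2. Other differences moved without a call. Neuropeptide genes differed by -0.14 without TLQP21 1 and -0.02 without Saline 4, and nerve growth genes by -0.13 without TLQP21 3. Skeletal muscle genes differed by -0.25 without TLQP21 2, and intestinal genes by -0.09 without Saline 3. Lipolysis genes differed by -0.10 without Saline 1 and -0.01 without Saline 2, and ductal genes by -0.01 without TLQP21 4. Without Saline 3, hypoxia (-0.20), matrix protease (-0.23) and islet (-0.35) genes passed. Without Saline 4, epithelial-mesenchymal transition (0.07), endothelial (0.13), cholesterol (0.06), mesothelium (0.27) and mitochondrial genome (-0.12) lists passed. Cholesterol genes also passed without TLQP21 1 (0.10) and TLQP21 3 (0.06), mesothelium without TLQP21 3 (0.38) and TLQP21 4 (0.29), and mitochondrial genome (-0.15) and adipocyte (-0.49) genes without TLQP21 4. Without Saline 2 and TLQP21 4 together, mast cell and eosinophil (-0.47) and mesothelium (0.29) lists passed. There too the split by sex-linked transcripts was uneven between the treatments.

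Over all 44 lists, camera with an estimated correlation passed 0 (3 with an unadjusted p under 0.05), fry 0 (0 with an unadjusted p under 0.05, smallest adjusted p = 0.915) and the exact permutation test of levels 0 (smallest adjusted p = 0.849). The permutation test could hardly pass after adjustment, because no exact p can lie below 0.0286 and 44 lists were adjusted together. Before adjustment its smallest p was 0.0571. The median estimated correlation was 0.247 and the highest 0.904, in the acinar list. Of the 19 lists called at the preset correlation, 17 differed in the same direction within the libraries with Xist and within those with Y-linked transcripts. The exceptions were acinar genes (0.09 and -0.85) and fibroblast genes (0.20 and -0.04). The choice of called lists favours equal directions, because the whole difference is the mean of the differences within the 2 kinds. Some lists differed little within 1 kind, such as hepatocyte (-2.93 and -0.02) and T cell genes (-0.04 and -0.27). The median and mean fold change of members differed in sign for adipocyte, ductal, lipolysis and Schwann cell genes. Camera's direction was opposite to the difference in level for Wnt, RAS-MAPK, Schwann cell and endothelial genes, none of them called.

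**Figure D4:**
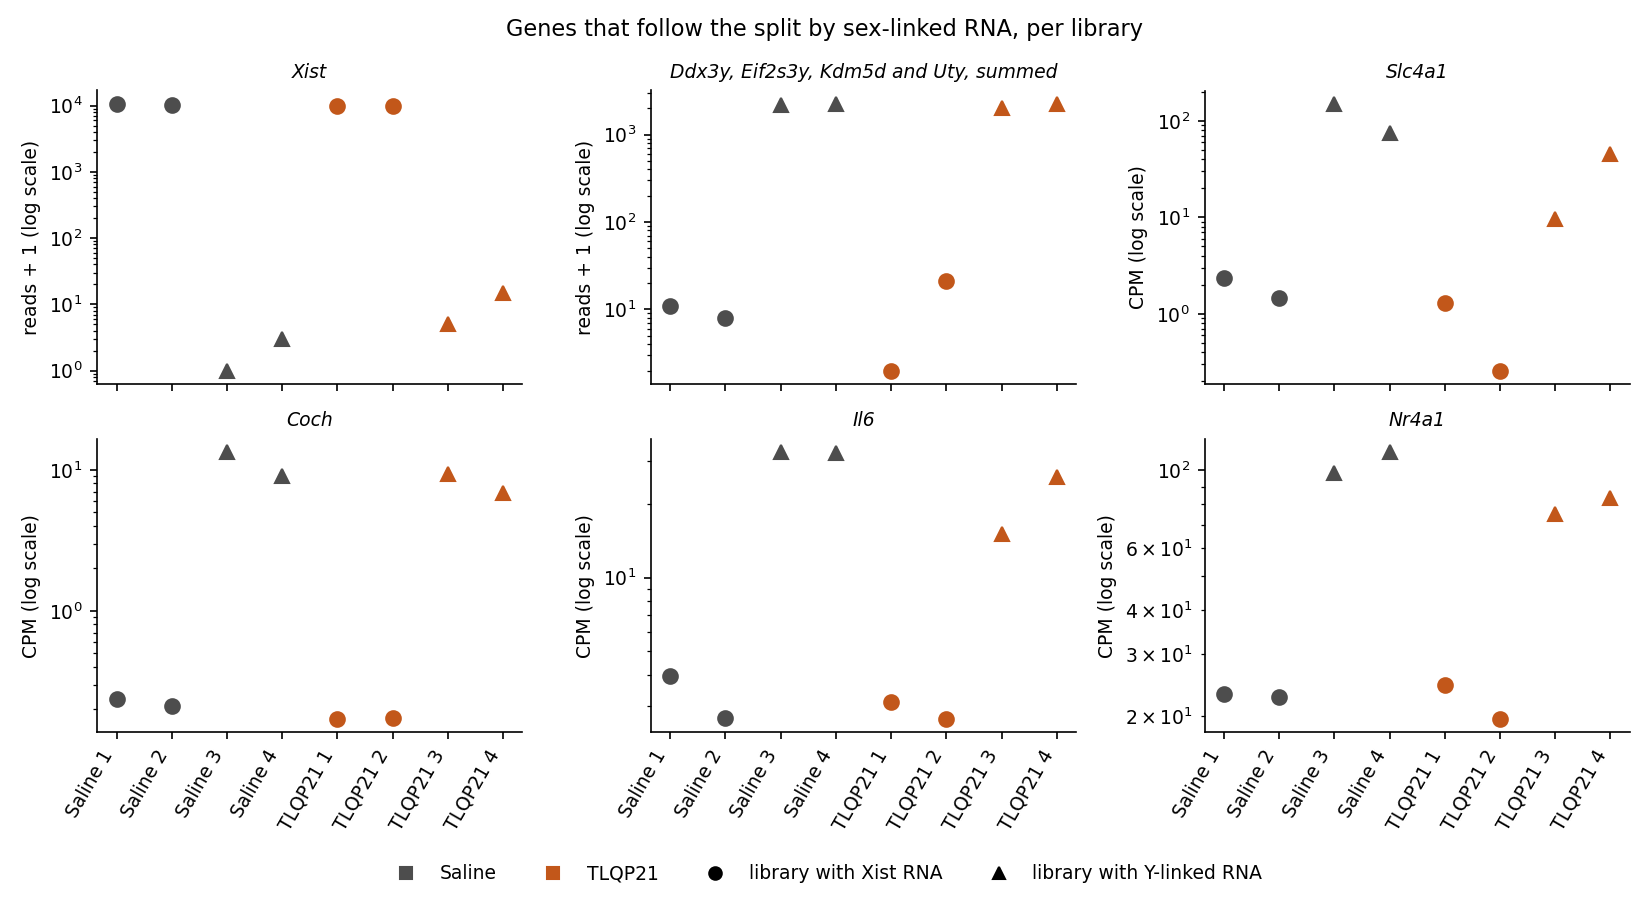
Reads plus 1 of Xist and of 4 summed Y-linked genes, and CPM of Slc4a1, Coch, Il6 and Nr4a1 (vertical axes, log scale) in each library (horizontal axis); grey is Saline, orange TLQP21, circles libraries with Xist RNA and triangles those with Y-linked RNA. Libraries 1 and 2 of each group have 9960 to 10625 Xist reads, libraries 3 and 4 have 0 to 14, and the 4 other genes are higher in every library with Y-linked RNA.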

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

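The tests of Saline 4 alone, of a lower share of all immune cells, of liver RNA and of splits balanced over sex-linked transcripts were chosen only after the results were seen; the counts over all splits of the libraries were planned. For single genes that count decides nothing, because the treatment split called 0 genes by edgeR and all 35 splits call at least as many (highest other 63, the split by sex-linked transcripts, a structure of the samples). For the number of lists that passed at the preset correlation, chance could not be excluded. Of the 35 splits of the 8 libraries, 12 passed at least 19 lists (highest other split 25). So did 6 of the 18 splits with 2 libraries with Xist on each side. Both counts include the treatment split itself. A library stood apart by its gap to the nearest of its group in 28 of 262 groups of 4 values, where chance gives about 13.1. These were 2 library measures, 5 list levels and 21 genes.

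The lower neutrophil and cytokine lists in TLQP21 were a pattern in which Saline 4 stood apart, at 5.58 log2 CPM for neutrophil genes (4.02 to 4.10 in the other Saline libraries) and 5.69 for cytokine genes (4.63 to 4.72). Against Saline 4 as the whole source, the mean difference of both lists was -0.51 without it and -0.83 with it. The lower level was not common to all TLQP21 libraries, since TLQP21 1 (4.06 and 4.72) lay within the range of the other Saline libraries. A lower share of all immune cells in TLQP21 tumours and an effect of the peptide on inflammatory cells, which no test here told apart, stayed open: the neutrophil level minus the T cell level, which such a share would leave alike, differed by -0.88 (TLQP21 minus Saline, exact permutation p = 0.0857). Exact permutation of the neutrophil and cytokine levels gave p = 0.0571 and 0.0857, so chance stayed open as well.

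Hepatocyte transcripts in Saline 2 were another pattern, with 0.644% of its counts in these genes (0.0321 to 0.0678% in the other Saline libraries) and a list level of 7.34 log2 CPM (0.99 to 1.24). Of the 20 hepatocyte genes, 18 lay at least 10 times above the highest other library, with 72633 reads of Alb. This is consistent with liver tissue or liver RNA in that sample, a hypothesis from the same data; no biological explanation was tested. Apob and Trf were the exceptions, and Apob is also expressed in the other libraries (501 ± 134 CPM in TLQP21). Without Saline 2, 0 of 11 hepatocyte genes passed adjusted over the list alone in the edgeR test (smallest adjusted p = 0.380).

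Among hepatocyte genes, Saline 2 also stood apart in Hpx (666 CPM), Ahsg (316), Apoa1 (258) and Serpina1b (133), and among complement genes in Hc (47.7 CPM). Saline 4 stood apart in S100a9 (328 CPM), Mmp9 (108), Hspa1a (285), Hspa1b (689), Prss3 (95.8), Bdkrb1 (7.34) and Col6a3 (198). Saline 3 had less Ly6c2 (12.9 CPM, against 23.1 to 25.2). TLQP21 1 stood apart in Ighv1-39 (26.8 CPM), Ighg2c (244), Nfkbia (153) and Gbp5 (116). TLQP21 2 had 0.633 CPM of Lime1 (0.401 to 0.432 in the other TLQP21 libraries). TLQP21 3 had the lowest hypoxia and glycolysis level of its group (7.63 log2 CPM, against 7.74 to 7.75). TLQP21 4 had 2.80% of its counts in mitochondrial transcripts (1.83 to 1.98% in the others) and a myofibroblast level of 4.44 (4.59 to 4.62). In single genes it stood apart in Cdh17 (279 CPM), Ube2c (103.3) and Vegfa (556).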

How the results depend on the processing

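Tests with the split by sex-linked transcripts as a covariate, with thinned libraries, or with Saline 2 and TLQP21 4 both left out were chosen only after the data were seen. The count of genes higher in TLQP21 was 0 in every alternative run, including DESeq2. Genes lower numbered 4 with DESeq2 and 1 with limma's voom with quality weights, and 0 in the other alternatives. The 19 lists became 0 with an estimated correlation, 0 with fry, and 0 with the split as a covariate and an estimated correlation. The estimated correlation alone already gave 0, so the last of these says nothing about the split. The count was 12 without Saline 2 and TLQP21 4, and 11 to 21 with single libraries left out. The DESeq2 alternative was not run for the lists. List levels with an exact p under 0.05 numbered 0, but 1 without a gene filter, 1 with a mean of at least 1 CPM, and 0 to 4 with single libraries left out. Measures per library with an exact p under 0.05 numbered 1, and 0 to 1 with single libraries left out; the 0 without Saline 2 and TLQP21 4 says nothing, since 3 libraries against 3 cannot give an exact p under 0.1. For results with a direction, 749 list values and 1706 gene values kept direction and side of the threshold, while 45 list values lost the call and 36 list and 5 gene values gained it. The cause was not tested.

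Directions turned in 49 list and 11 gene values. With library size alone these were RAS-MAPK (0.0212), endothelium (0.000214), Schwann cell (0.0169) and Wnt (0.0103). Others were Schwann cell without a filter (0.0385) and with thinned libraries (0.00117), Wnt with a mean of at least 1 CPM (0.0275), and epithelial-mesenchymal transition with acinar genes left out (-0.00338). With the acinar level as a covariate, Ctrb1 (0.0302) and Apob (-0.0350) turned. Without Saline 2 and TLQP21 4 together, Hpx (0.28), Hc (0.0694), cell cycle (-0.0113), oxidative phosphorylation (0.0339), cholesterol (-0.0307), epithelial-mesenchymal transition (-0.0358), endothelium (0.0082), cytotoxic (0.0156), B cell (0.11), skeletal muscle (0.0140) and Wnt (0.0852) turned. The cause was not tested, except that the level of Hpx, a hepatocyte gene, and of Hc stood apart in Saline 2. Leaving out Saline 2 and TLQP21 4 together also made the split by sex-linked transcripts uneven between the treatments. Of the lists that turned in that fit, cell cycle, cytotoxic and oxidative phosphorylation separated completely along the split. Whether the unevenness turned them was not tested.

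With single libraries left out, directions turned within these ranges: RAS-MAPK -0.0458 to 0.0435, hypoxia -0.20 to 0.0517, epithelial-mesenchymal transition -0.0512 to 0.0744, hepatocyte -2.03 to 0.0831, fibroblast -0.00074 to 0.19, dendritic -0.13 to 0.0321, Schwann cell -0.0422 to 0.0434 and immediate-early -0.42 to 0.0118. Matrix proteases ran from -0.23 to 0.0157, endothelium -0.12 to 0.13, acinar -0.67 to 0.0506, acinar injury -0.27 to 0.0227, islet -0.35 to 0.10, Wnt -0.0703 to 0.0936, TGF-beta -0.0774 to 0.0046 and mesothelium -0.13 to 0.38. Mitochondrial genome transcripts ran from -0.15 to 0.0064, adipocyte -0.49 to 0.16, oxidative phosphorylation -0.0618 to 0.0128 and cholesterol -0.0231 to 0.10. Among genes, Hpx ran from -7.81 to 0.0854, Hc -3.47 to 0.24, C3ar1 -0.13 to 0.26, Ctrb1 -0.73 to 0.13 and Apob -0.0813 to 0.27. The cause was not tested.

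With the replicate number as a block (replicate block), 0 genes were higher and 0 lower, and 20 lists passed. Deviations of same-numbered libraries correlated at 0.115, 0.194, 0.271 and -0.0533, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Same-numbered libraries do share the side of the split by sex-linked transcripts.

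At this depth Vgf, with 24 and 44 reads per group, did not pass the filter on low counts and was not tested.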

Other observations

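All tests along the split by Xist and Y-linked transcripts were chosen only after the split was seen.

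The 4 libraries with Y-linked transcripts differed from the 4 with Xist in many genes outside the sex chromosomes, in both treatment groups. Genes of red cell precursors were higher in them: the anion exchanger Slc4a1 was at 69.9 ± 59.8 CPM against 1.35 ± 0.871 (log2 fold change 5.58, n = 4 libraries each) and the erythroid gene Hemgn at 10.7 ± 8.13 against 0.163 ± 0.157. Immediate-early genes were also higher: Nr4a1 was at 92.5 ± 16.6 against 22.4 ± 2.04 CPM, Fosb at 66.6 ± 32.3 against 5.75 ± 0.317, Egr1 at 103 ± 21.2 against 45.5 ± 4.34. Il6 was at 26.3 ± 8.12 against 3.10 ± 0.626 CPM and Ptgs2, an inducible prostaglandin synthase, at 96.2 ± 27.1 against 29.4 ± 11.7, while the cytokine and chemokine list differed by 0.14 and did not pass camera at the preset correlation (adjusted p = 0.0659) or with an estimated one (0.899). Coch, an extracellular matrix gene, was at 9.65 ± 2.69 against 0.198 ± 0.0323 CPM. Lower in them were the NK receptor ligand gene Clec2d (43.7 ± 6.41 against 87.0 ± 8.66 CPM), Cd52 (47.3 ± 11.8 against 90.1 ± 10.8), the chemokine Ccl5 (23.5 ± 13.9 against 75.9 ± 45.4) and Rpl38 (164 ± 34.96 against 345 ± 24.4).

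With treatment in the same edgeR fit, 68 genes passed along the split (44 higher and 24 lower with Y-linked transcripts), 61 of them outside chromosomes X and Y. No gene passed in the edgeR interaction of split and treatment, with 876 at an unadjusted p under 0.05 and a smallest adjusted p of 0.842. The other tools were not run on it. It rested on 2 libraries per kind and treatment, and its recovery was not simulated. The lack of calls therefore does not show that treatment acted alike in both kinds. Erythrocyte and platelet (1.92), immediate-early and heat-shock (0.75) and cell cycle (0.25) lists were higher in every library with Y-linked transcripts than in every library with Xist. Cytotoxic and NK (-0.72), ribosomal protein (-0.12) and oxidative phosphorylation (-0.12) lists were lower in every one. These were 6 of 44 lists, where chance alone would give about 1.26. In camera with the preset correlation all but oxidative phosphorylation (adjusted p = 0.0530) passed along the split. Lists that passed without complete separation included interferon response (-0.40, adjusted p = 6.02e-14, the smallest of all lists), antigen presentation (-0.27, 3.44e-07), macrophage (-0.40, 3.96e-06) and complement (-0.32, 0.000372). For every list named in this paragraph the difference along the split was larger in size than that between treatments. With an estimated correlation none of them passed. The adjusted p was 0.433 for erythrocyte, immediate-early, cell cycle, cytotoxic and interferon lists, and 0.633 for antigen presentation. It was 0.624 for macrophage, 0.587 for complement, 0.529 for ribosomal protein and 0.587 for oxidative phosphorylation.

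For the erythroid and immediate-early genes along this split, chance was made less likely but was not excluded. Without treatment in the fit, 1 of 35 splits of the libraries, the split itself, called as many as its 57 genes outside X and Y (highest other split 8). A count of 1 is the smallest possible, and the test was chosen after the split was seen. It also counted every called gene outside X and Y, and genes that vary together can be called together. Spleen tissue in these samples stayed open, since B cell follicle genes differed by 0.30 with an exact permutation p = 0.6, and other values went both ways: the splenic macrophage gene Itgad was higher with Y-linked transcripts (2.27 ± 1.19 against 0.216 ± 0.107 CPM, adjusted p = 0.0201 by edgeR), as was Spic (3.03 to 5.66 against 0.892 to 1.82 CPM, not called), while the B cell and plasma cell list was lower (-0.46, adjusted p = 0.0257 by camera at the preset correlation and 0.897 with an estimated one). Handling or collection order could not be told apart from the split, because replicate number and sex-linked transcripts matched in 8 of 8 libraries. Sex of the animals, which the labels do not give, stays among the open explanations as untested.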
